A study of Mus musculus with 3 samples.

How the data were processed

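RNA from CH12 cells, a mouse B lymphoma line, was measured by mRNA sequencing in 3 libraries. The labels describe a control library and libraries of cells treated with 5 ng/ml TGFb for 6 h or 24 h, with 1 library per group. Per the labels' protocols, total RNA was extracted, poly(A) mRNA was isolated on magnetic beads, libraries followed an Illumina RNA-seq protocol, and sequencing ran for 50 cycles. The submitters' processing notes name CASAVA 1.8.2, STAR, RSEM and bedtools and the genome build mm10. Other versions, the gene annotation, the strand setting and whether fragments were sequenced from both ends are not given in the sources used here.

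The deposited tables hold, per the file headers, an expected count, a TPM value and an FPKM value for each of 24901 gene rows, listed with RefSeq transcript accessions. The expected counts deposited by the authors are RSEM estimates, which share out reads that fit several genes and so need not be whole. The deposited TPM values were made by the authors' RSEM run, scaled to the transcript length left after the fragment length is taken off, and sum to the same total in each library. The FPKM values deposited by the authors were not used here. All counts lay in the 20668 protein-coding rows. The other 4233 rows, 92 spike-in rows among them, held 0 counts in each library, so noncoding RNAs and spike-ins were not analysed here. Immunoglobulin heavy chain constant regions and mitochondrially encoded genes were not analysed here either.

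Expected counts were rounded to whole numbers, which moved library totals by at most 3e-05%. Libraries were scaled by TMM factors from edgeR 4.0.16 in R 4.3.3 (0.9459 for control, 1.0015 for 6 h and 1.0556 for 24 h), and values are given as normalized CPM (counts scaled to library size). Totals after rounding were 51386096 counts in control, 64229808 at 6 h and 27487231 at 24 h. A single count was worth 0.0195, 0.0156 and 0.0364 CPM in these libraries. A gene was measured if it had at least 1 CPM and 30 counts in at least 1 library, which left 10754 genes. Of these, 1239 (11.5%) had an expected count that was not whole in some library, which marks reads shared with another gene, and named genes among them are pointed out.

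With 1 library per group, no error between cultures can be estimated, so no test was run and no p-value is given. Genes were counted by a rule of size: at least 2-fold apart, with at least 1 CPM and 30 counts in the higher library, and a count of 0 set to a floor of 3 counts. Fold values carry the exact conditional 95% interval (Clopper-Pearson) of a ratio of counts. These intervals cover counting error only, and reads without molecular identifiers are not independent molecules. The 3 comparisons were 6 h against control, 24 h against control and 24 h against 6 h. The first 2 share the control library, so their overlap was set beside the overlap of independent lists and beside 50 simulated sets of unchanged libraries with assumed extra coefficients of variation.

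The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named 15 genes in advance, of which Igha and Ighm were not analysed here. It added the 12 highest and 12 lowest genes in each comparison with control and the 5 highest and 5 lowest at 24 h against 6 h, ranked by the log2 ratio of CPM + 1 among genes that passed the size rule. Symbols of predicted or uncharacterised models were left out. Up to 4 members were named per gene list, by the same ranking. Some genes that the rule named are not reported here. Other genes were named after their values were seen, and the text says so. There were 26 lists. Of each list with at least 4 measured members, the median log2 ratio was compared with 10000 random lists of the same size matched on mean expression in 20 bins, and its percentile describes these libraries only. Positions are those of the RefSeq annotation of GRCm38.p6, the assembly that mm10 holds, matched by transcript accession for 10732 of the 10754 measured genes, counted from 1.

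The rule was tested on simulated data drawn from the real means and totals over 24901 genes. For 6 h against control with an assumed extra coefficient of variation of 0.1, it recovered 96.0% of 50 genes set 2.5-fold apart and 0.0% of 50 genes set 1.5-fold apart. For 24 h against control it recovered 94.0% and 8.0%. The genes set apart were drawn from genes above a minimum CPM in control, so these shares do not cover genes with few control counts. With the same assumed spread, the counting interval held a ratio of 1 for only 39.1% of unchanged genes at 6 h and 45.6% at 24 h. Of 200 random lists of 20 genes, 5.0% fell in the outer 5% of percentiles. These lists came from the same genes as the lists they were compared with, so a share near 5% was built in. It does not cover lists whose members move together.

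Alternatives were DESeq2 1.42.0 size factors, total counts, upper quartile scaling, the deposited TPM, no minimum beyond 1 count, a minimum of 5 CPM, 1.5-fold and 3-fold limits, a ratio of CPM + 1, and a counting interval that excludes a ratio of 1. For gene counts with the deposited TPM, the minimum was 1 TPM in the higher library, in place of the CPM and count minimum. Removal of the trend with transcript length, as medians of 20 length bins, and removal of genes that share reads were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.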

Results

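CH12 cells are a mouse B lymphoma line that can switch its immunoglobulin class in culture, and TGFb is a cytokine that signals through Smad proteins. The series is titled for the binding of Smad3 and Smad7 in this line, and the part described here measured mRNA. The 3 libraries were a control, cells treated with TGFb (5 ng/ml) for 6 h and cells treated for 24 h, with 1 library each. They held 51386096, 64229808 and 27487231 counts, and 14070, 14499 and 13893 genes had counts. No difference below has a replicate check. The labels used here give no time for the control, and no library labelled as untreated at 24 h was analysed here. Time in culture thus cannot be told apart from treatment.

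The comparison at 6 h asked which mRNAs differed early in TGFb treatment. Some genes of the TGFb pathway itself were higher. Tgfbr1, the type I receptor (chromosome 4, 47353222 to 47414926), had 40.9 CPM in control and 225 CPM at 6 h, 5.51-fold higher (interval 5.26 to 5.78). Skil, a repressor of Smad activity (chromosome 3, 31095058 to 31122923), was 3.93-fold higher (3.74 to 4.14). Smad7, the inhibitory Smad that is itself a Smad target (chromosome 18, 75367365 to 75395935), was 2.06-fold higher (1.94 to 2.19).

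The genes furthest above control at 6 h included others tied to receptors or signalling. Ifnlr1, a receptor chain for type III interferons, had 0.658 CPM in control and 16.7 CPM at 6 h, 25.4-fold higher (17.9 to 37.4). Nrarp, an inhibitor of Notch signalling, was 9.02-fold higher (7.72 to 10.6), and the chemokine receptor Ccr1 was 4.84-fold higher (4.37 to 5.37). Adamtsl2 had 6 counts in control and 730 at 6 h, 91.9-fold higher with a wide interval of 42.0 to 251. Rgs16 was 19.7-fold higher, Mpzl2 12.5-fold, Spsb1 11.2-fold, the collagen gene Col15a1 8.09-fold and Rp1l1 7.71-fold. Ttc8 was 5.34-fold higher and Abca1, a cholesterol exporter, 5.12-fold.

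Cd22, an inhibitory coreceptor of B cells (chromosome 7, 30865404 to 30880342), was the lowest gene at 6 h by the ranking used. It had 139 CPM in control and 37.0 CPM at 6 h, 3.76-fold lower (3.59 to 3.95). The calcium channel gene Cacna1h was 3.0-fold lower (2.64 to 3.42). The transcription factor genes Nfil3, Pou2f3 and Batf3 were 2.75-fold, 2.73-fold and 2.41-fold lower, and Ehf was 2.17-fold lower. Plk2, D1Ertd622e, Cited4, Serpinb6b and Nrros were lower by 2.53-fold, 2.66-fold, 2.43-fold, 2.34-fold and 2.19-fold. Ovol3 was 2.87-fold lower but shared reads with another gene.

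Of the 26 measured TGF-beta target genes on the list fixed in advance, 7 were at least 2-fold higher, 0 were lower, and 25 had a ratio above 1. The list's median log2 ratio was 0.53, at percentile 100 of the matched random lists. Spsb1, Ldlrad4, Skil and Id2 stood furthest out, with log2 ratios of 3.48, 2.47, 1.97 and 1.71. Of 19 receptors, ligands and Smads, 4 were higher (Tgfbr1, Smad6, Acvr1b and Smad7), with a median of 0.18 at percentile 96.8, or 74.5 with the length trend described below removed, and 5 of the 19 had a ratio below 1. Smad3 was near its control level (7.55 and 7.28 CPM), and the sign of this small difference turned with total counts and TPM. Tgfb1 was 1.11-fold higher (1.08 to 1.14) and Tgfbr2 1.88-fold (1.82 to 1.94), under the limit of 2-fold.

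Genes of Myc and of ribosome biogenesis, which supply growing cells with ribosomes, were lower together at 6 h. All 25 measured members had a ratio below 1, none reached 2-fold, and the median was -0.45, at percentile 0.0. Myc had 593 CPM in control and 335 CPM at 6 h, 1.77-fold lower (1.74 to 1.8), and Srm, Rrp9 and Nop16 had log2 ratios of -0.79, -0.70 and -0.66. Of 22 cholesterol synthesis genes, 21 had a ratio below 1, with a median of -0.27 at percentile 0.01, and Mvd and Msmo1 had log2 ratios of -0.59 and -0.53. Of 22 genes of the ATF4 and unfolded protein response, 16 had a ratio below 1 (median -0.25, percentile 0.13), with Sdf2l1 at -0.70.

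Adhesion and homing receptors were mixed at 6 h. Of 22 measured, 6 were higher, among them Itga6, Cxcr4, Ccr6 and Cxcr3, and 7 had a ratio below 1. The median was 0.43 at percentile 99.99, with an interval over members from -0.15 to 1.08. Cxcr4, a chemokine receptor, had 36.7 CPM in control and 124 CPM at 6 h. Cxcr3 reached only 1.803 CPM. Of 25 G2 and M phase genes, 0 passed the limit, and their median of 0.11 lay at percentile 99.75.

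By the size rule, 258 genes were higher and 39 lower at 6 h (86.9% higher), out of 10754 measured. The log2 ratios went with transcript length across genes (Spearman's rho 0.397 over these genes, which are not independent replicates). With that trend removed, an alternative chosen after the data were seen, 245 genes were higher and 37 lower, and 226 and 29 of them were genes counted without the removal.

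At 24 h, the comparison with control asked which mRNAs differed late in treatment. The 3 pathway genes described at 6 h were above control here too. Tgfbr1 reached 295 CPM, 7.21-fold above control (6.87 to 7.58), Skil was 4.61-fold higher (4.36 to 4.86), Smad7 2.64-fold (2.47 to 2.82) and Tgfbr2 2.10-fold (2.02 to 2.18). Runx3, a transcription factor gene that TGFb is known to act on, was 1.74-fold higher (1.68 to 1.79), and Id3 was 1.90-fold higher (1.82 to 1.98). Cd22 had 15.6 CPM and was 8.94-fold lower than control (8.13 to 9.85).

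Further genes stood far above control at 24 h. Rp1l1 had 6.11 CPM in control and 184 CPM at 24 h, 30.1-fold higher (26.8 to 34.0), and Ccr1 was 14.5-fold higher (13.2 to 16.1). Adamtsl2 was 96.0-fold higher (43.7 to 264), from 6 counts in control, and Lrig1 was 56.3-fold higher (30.2 to 118), from 10 counts. Scel was 44.7-fold higher, Ifnlr1 27.5-fold, St8sia1 22.5-fold, Cd7 21.5-fold and the kinase gene Rps6ka2 16.6-fold. Ctsw, a cathepsin gene, was 14.7-fold higher, Rab37 13.8-fold and Nrarp 11.8-fold. Itgae, an integrin gene that TGFb acts on in T cells, had only 32 counts at 24 h and was 2.68-fold higher (1.49 to 4.94).

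Lower genes at 24 h included Wnt10a, a secreted signalling factor, with 156 CPM in control and 26.3 CPM at 24 h, 5.93-fold lower (5.5 to 6.39). Ehf was 5.76-fold lower, Cacna1h 5.70-fold, D1Ertd622e 5.16-fold, Slc5a9 5.09-fold, Nrros 4.61-fold, Serpinb6b 4.13-fold, Mcoln2 4.11-fold and Batf3 3.75-fold. Eif3j2, which codes for a translation initiation factor subunit, was 12.3-fold lower (11 to 13.8), but it shares reads with its near copy Eif3j1. Ovol3 was 8.58-fold lower (5.17 to 15.3), also with shared reads. Bcl2l11, a pro-apoptotic gene, was 1.27-fold higher (1.20 to 1.33).

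Of the TGF-beta target genes, 10 of 26 were higher and 0 lower at 24 h, with a median of 0.72 at percentile 100. Ldlrad4 had 2.43 CPM in control and 22.1 CPM at 24 h, and Smad6 had 2.76 and 9.17 CPM. Of the receptors, ligands and Smads, 5 of 19 were higher, with a median of 0.23 at percentile 92.4, and 5 had a ratio below 1. Smad3 was 1.64-fold lower (1.34 to 2.01) and Tgfb1 1.17-fold higher (1.13 to 1.21). The class switch recombination list, of 26 measured genes, had a median of -0.09 at 6 h and -0.13 at 24 h, a direction that turned with the deposited TPM at both times and with total counts at 24 h, and its percentiles were 20.1 and 34.3. Apex1, Ung and Runx3 had log2 ratios of -0.77, -0.71 and 0.80 at 24 h.

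The Myc and ribosome biogenesis genes stood further below control at 24 h. All 25 had a ratio below 1, 7 were at least 2-fold lower, and the median was -0.93 at percentile 0.0. Odc1, which makes polyamines, had 1955 CPM in control and 667 CPM at 24 h, 2.93-fold lower (2.89 to 2.98). Myc was 2.10-fold lower (2.05 to 2.15), and Srm and Nop2 had log2 ratios of -1.42 and -1.08. The list kept its sign under each scaling tried, and its median was -0.81 with the length trend removed. Genes of the ATF4 and unfolded protein response had a median of -0.62 at percentile 0.0, with 2 of 22 lower. These were Sdf2l1 and Creld2, and the chaperone genes Hsp90b1 and Hspa5 had log2 ratios of -0.99 and -0.89. Glycolysis and hypoxia genes had a median of -0.38 at percentile 0.88, with Vegfa lower, Ddit4 higher and Ldha at -0.93. Heat shock genes had a median of -0.56 at percentile 0.26, and at 3.17 with the length trend removed. Hspd1 had a log2 ratio of -0.93 and shared reads.

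MHC class II genes, which serve antigen presentation, were above control at 24 h. Myeloid markers, described below, were above control in the same library, with 5 of 7 at least 2-fold higher. Some of them mark cells that also carry MHC class II, and a link between these lists was not tested. All 11 measured MHC class II genes had a ratio above 1, 2 were at least 2-fold higher, and the median was 0.63 at percentile 99.98. H2-Ob had 9.26 CPM in control and 90.3 CPM at 24 h, and Ciita, the activator of this gene family, had 72.0 and 182 CPM. At 6 h the same list had a median of 0.06 at percentile 85.9, which lay at 99.98 with the length trend removed. Interferon response genes had a median of -0.05 at 6 h, positive with total counts and TPM, and of 0.83 at 24 h, at percentile 99.83. Of 18 measured, 4 were higher at 24 h, among them Mx1, Oasl2 and Oas2, named after their values were seen, and 1 was lower. Bst2 had 53.6 CPM in control, 36.0 at 6 h and 24.0 at 24 h.

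B cell genes were mixed. Of 23 B cell identity genes, 4 were higher at 24 h (Bach2, Fcrla, Ikzf3 and Pou2f2) and Cd22 was lower, with a median of 0.03 at 6 h (percentile 94.5) and 0.27 at 24 h (percentile 99.97). Bach2, a repressor of plasma cell fate, had 12.3 CPM in control, 37.2 at 6 h and 61.4 at 24 h. Of 11 germinal centre genes, which include Bach2, 5 were higher at 24 h, with a median of 0.96 at percentile 99.99 and an interval over members from -0.56 to 2.05. At 6 h its median was 0.15 at percentile 89.1, and -0.01 with a minimum of 5 CPM. Plasma cell genes had a median of -0.12 at 6 h, positive with TPM, and -0.26 at 24 h, at percentiles 14.9 and 12.2. Fkbp11 and Jchain, the joining chain of IgA and IgM, were lower at 24 h, Jchain from 454 to 174 CPM, and Jchain was the 1 measured member of the immunoglobulin list.

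Adhesion and homing receptors had 8 of 22 members higher and 2 lower at 24 h, with a median of 0.75 at percentile 100 and an interval over members from -0.22 to 1.42. By the ranking on CPM + 1, Ccr6, Cxcr4, Itga6 and Itgam stood furthest out, with log2 ratios of 2.49, 1.92, 1.47 and 1.91. Itgam is also on the list of myeloid markers described below, and the lower members were S1pr3 and Itgb3, named after their values were seen. S phase genes had a median of -0.09 at 6 h, positive with TPM, and -0.33 at 24 h, at percentiles 47.0 and 7.35, with 24 of 25 members below a ratio of 1 at 24 h and Ccne1 alone at least 2-fold lower. G2 and M phase genes had a median of -0.01 at 24 h, positive with total counts, upper quartile scaling and TPM, at percentile 92.4. Among cell cycle inhibitors and G1 cyclins, Btg1, Btg2, Cdkn2d and Rbl2 were higher at 24 h and Ccne1 was lower. Their medians were -0.05 at 6 h and 0.07 at 24 h, and the sign turned with total counts and TPM at 6 h and with the length trend removed at 24 h. Their percentiles were 40.2 and 85.3. Btg1, an antiproliferative gene, had 63.5 CPM in control and 247 CPM at 24 h.

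The Bcl2 family had medians of 0.06 and 0.19 at 6 h and 24 h, at percentiles 83.7 and 95.9, or 98.6 and 99.7 with the length trend removed. Bmf, a pro-apoptotic member, had 3.85 CPM in control, 9.30 at 6 h and 24.5 at 24 h. Immediate early and NF-kB response genes had medians of 0.07 and 0.18 at percentiles 83.7 and 91.6, with Nfkbiz and Btg2 higher and Dusp5 and Ccl4 lower at 24 h. The p53 targets had medians of 0.15 and 0.06 at percentiles 92.8 and 59.9, with Trp53inp1 higher and Plk2 lower. Cholesterol synthesis genes had a median of -0.14 at 24 h, positive with total counts and TPM, at percentile 35.5. Housekeeping genes had medians of -0.08 at both times, positive with total counts, TPM and the length trend removed, at percentiles 77.9 and 94.4. Glycolysis and heat shock genes had medians of -0.14 (positive with TPM) and -0.23 at 6 h, at percentiles 14.7 and 2.81.

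Markers of other cell types were few and mostly low. Of 16 myeloid markers, 7 were measured and 5 of these were higher at 24 h, with medians of 0.30 at 6 h and 1.37 at 24 h, at percentiles 89.6 and 99.96. Adgre1 had 2.04 CPM in control and 12.9 at 24 h, and Csf1r had 8.33 and 25.8 CPM. All 4 measured fibroblast and endothelial markers were higher at 24 h, with medians of 1.04 and 1.999 at percentiles 99.2 and 99.8. Pecam1 stood at 7.34 CPM and Col1a1 at 1.07 CPM at 24 h. Of 4 measured T cell markers, Cd4 was lower at both times and stood at 1.03 CPM at 24 h, while Lck had 153 CPM in control and 259 CPM at 24 h. Their medians were 0.33 and 0.72 at percentiles 90.1 and 93.2.

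**Figure D1:**
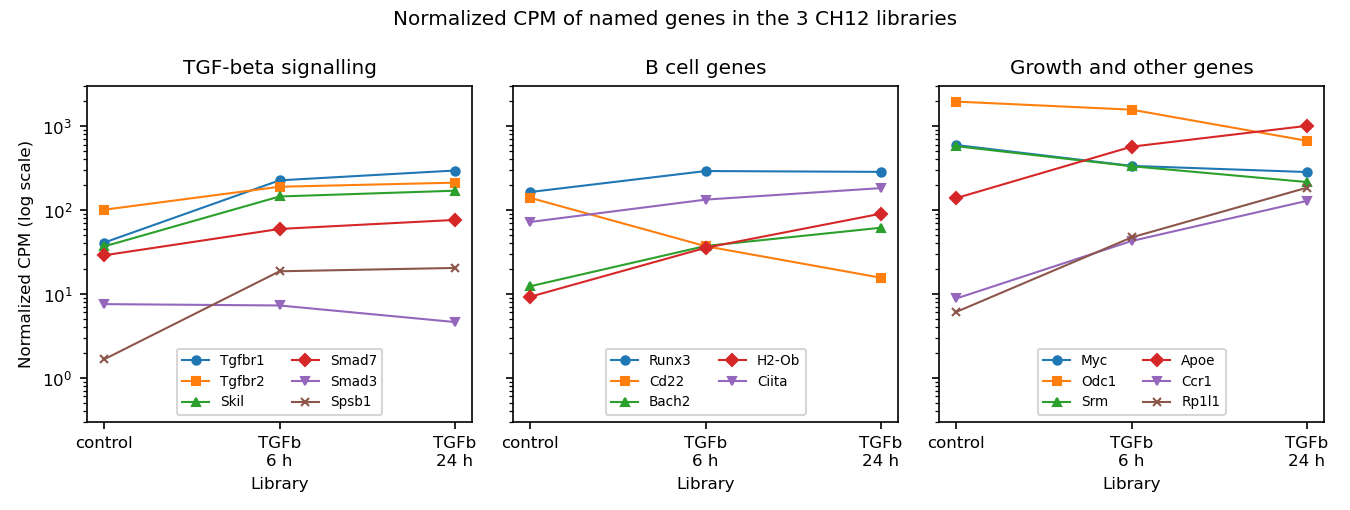
Normalized CPM (log scale) of 17 named genes in the 3 libraries, 1 point per library, with lines joining the values of a gene. Tgfbr1 went from 40.9 CPM in control to 225 at 6 h and 295 at 24 h, while Cd22 went from 139 to 37.0 and 15.6 CPM, and Apoe, chosen after its values were seen, stood at 1006 CPM at 24 h.

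By the size rule, 797 genes were higher and 217 lower at 24 h, so 78.6% of the genes counted were higher. With total counts the split was 1075 and 118 (90.1% higher). With the deposited TPM, which had its own minimum, it was 1236 and 84 (93.6% higher). Relative to TMM scaling, these 2 scalings moved the median gene by 0.158 and 0.265 on the log2 scale at 24 h and by 0.082 and 0.158 at 6 h. At a limit of 1.5-fold the split was 1808 and 1274, or 58.7% higher. The log2 ratios went with transcript length at 24 h too (rho 0.385 across genes). The shortest of 20 length bins had a median of -0.37 and the longest 0.50. With the trend removed, 750 genes were higher and 168 lower, and 655 and 133 of them were genes counted without the removal. Some list percentiles also crossed into the outer 5% of random lists with the removal. At 6 h these were MHC class II and the Bcl2 family, as given above, B cell identity (99.19), the immediate early and NF-kB response (99.75), housekeeping (98.02) and the interferon response (1.26). At 24 h they were the Bcl2 family, as given above, and the plasma cell list (1.99). At 24 h against 6 h the Bcl2 family crossed into it (93.3 to 99.5) and the fibroblast and endothelial list out of it (97.6 to 96.3).

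**Figure D2:**
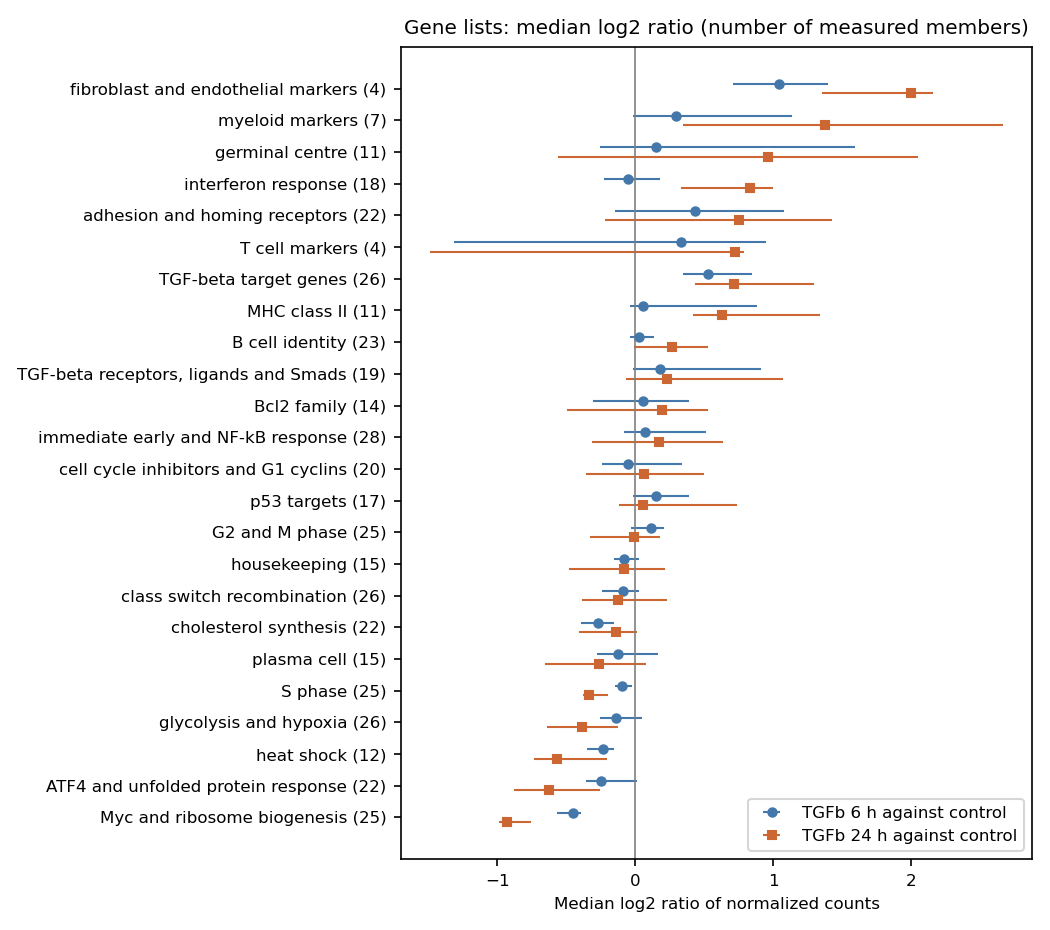
Median log2 ratio of each gene list with at least 4 measured members at 6 h (circles) and 24 h (squares) against control. The number of measured members is in brackets. Bars are 95% order-statistic intervals over the members, or the whole range for lists of 4 members, and carry no error between cultures. The Myc and ribosome biogenesis list lies lowest, at -0.45 and -0.93, with no sign change under any scaling tried.

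**Figure D3:**
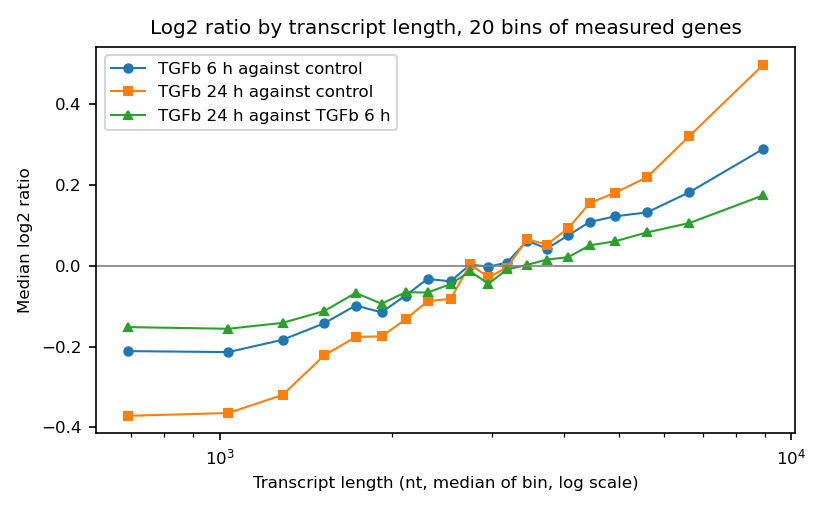
Median log2 ratio in 20 bins of measured genes by transcript length (nt, log scale), for the 3 comparisons. At 24 h against control the median goes from -0.37 in the shortest bin to 0.50 in the longest.

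Most genes counted at 6 h were also counted at 24 h. Of the 258 higher genes, 239 were higher at both times, Tgfbr1, Skil and Smad7 among them, and 31 of the 39 lower genes were lower at both, Cd22 among them. Independent lists of these sizes would share 19.1 and 0.79 genes. Simulated unchanged libraries against the same control shared a median of 0 higher and 0 lower genes at an assumed extra coefficient of variation of 0.1, 20 and 9 at 0.2, and 200 and 122.5 at 0.3. Their counts of higher and lower genes at 6 h had medians of 1 and 1 at 0.1, 101 and 102.5 at 0.2, and 619 and 615 at 0.3. At 24 h these were 3 and 4, 110.5 and 115.5, and 623 and 627. The 39 genes lower at 6 h were thus fewer than unchanged libraries gave at 0.2, and of these 4 counts only the 797 genes higher at 24 h were more than they gave at 0.3. The shared genes were 92.6% of those higher and 79.5% of those lower at 6 h. In the simulation at 0.3, the 200 and 122.5 shared genes stood beside far longer lists, of 619 and 615 genes at 6 h. The real coefficient of variation is not known, and part of the overlap may come from the shared control. Of the 797 genes higher at 24 h, 98.4% were above control at 6 h, and of the 217 lower genes 99.5% were below it. The same shares in the simulated unchanged libraries, taken after the data were seen, were 95.8% and 89.7% at 0.2, and 89.8% and 83.4% at 0.3, so a high agreement of signs shows little by itself. No gene was at least 2-fold higher at one time and 2-fold lower at the other.

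The comparison of 24 h with 6 h showed which genes stood further out late. Lrig1 was 8.01-fold higher at 24 h than at 6 h (6.35 to 10.2), Scel 5.92-fold (5.31 to 6.61), St8sia1 5.80-fold (4.79 to 7.06) and Cd7 4.73-fold (4.10 to 5.45). The integrin gene Itgax was 7.12-fold higher (5.63 to 9.08) and shared reads. Odc1 was 2.35-fold lower at 24 h than at 6 h (2.31 to 2.39), Wnt10a 3.19-fold (2.96 to 3.45), Ehf 2.65-fold (2.29 to 3.08) and Cd22 2.38-fold (2.15 to 2.63). Eif3j2 was 10.4-fold lower (9.36 to 11.7), with shared reads, while its sum with Eif3j1 was 1.25-fold lower. Smad7, Skil and Tgfbr1 lay within 1.5-fold of their 6 h levels.

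Among the lists, all 11 MHC class II genes were above their 6 h level, with a median of 0.48 at percentile 100, and H2-Ob was at least 2-fold higher. Interferon response genes had a median of 0.69 at percentile 100, with Mx1 higher but at 2.38 CPM. Myeloid markers had a median of 0.60 at percentile 99.69, with Adgre1 and Itgam higher. The germinal centre list had a median of 0.26 at percentile 98.98, but -0.09 with a minimum of 5 CPM. All 25 Myc and ribosome biogenesis genes were below their 6 h level, with a median of -0.36 at percentile 0.0. The medians of the ATF4 and unfolded protein response, glycolysis and S phase lists were -0.41, -0.25 and -0.23, at percentiles 0.0, 0.07 and 0.62.

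In all, 202 genes were higher and 40 lower at 24 h than at 6 h. Of the 258 genes higher at 6 h, 91 stood at least 1.5-fold further up at 24 h, 156 lay within 1.5-fold of the 6 h value and 11 were back by 1.5-fold or more. Of the 39 lower genes, 15 stood further down, 21 lay within 1.5-fold and 3 were back. Pou2f3 was among the latter, with 13.6 CPM in control, 4.97 at 6 h and 9.27 at 24 h.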

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

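Removal of the length trend and of genes that share reads were the alternatives chosen after the data were seen. Of 96 gene counts under alternatives, 54 lay within 1.5 times the value reported and 42 did not. Of 498 list medians, 463 lay inside the interval over members, 34 moved out of it and 1 changed sign after standing apart from random lists. Of 882 log2 ratios of named genes, 680 lay inside the counting interval, 202 outside it, and none past 2-fold changed sign. DESeq2 size factors, upper quartile scaling, the counting interval, removal of the length trend and leaving out genes that share reads moved no gene count by over 1.5 times. The counting interval changed no call, since a 2-fold gap with 30 counts nearly always excludes a ratio of 1. Genes that share reads were only 11.5% of those measured. Both settings could thus hardly move a count and say little about stability. Depth limits the genes at a few CPM, of which the 24 h library, with 27487231 counts, holds the fewest reads.

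Gene counts follow in the order higher and lower at 6 h against control, higher and lower at 24 h against control, higher and lower at 24 h against 6 h, and higher and lower at both times. Without a minimum they were 835, 335, 1583, 438, 962, 239, 631 and 109, since more genes of few counts enter. At 1.5-fold they were 728, 230, 1808, 1274, 684, 227, 664 and 201, and at 3-fold 88, 4, 313, 37, 42, 6, 76 and 3, as the limit itself sets. With a minimum of 5 CPM, which leaves fewer genes, they were 153, 22, 502, 174, 88, 17, 144 and 19. With CPM + 1, which shrinks low genes, the values that moved were 162 and 20 at 6 h, 67 and 11 at 24 h against 6 h, and 148 and 16 at both times. With TPM, 24 genes were lower at 6 h, 1236 higher and 84 lower at 24 h, and 17 lower at both times, and with total counts 118 were lower at 24 h. Total counts shift all genes up by 1 factor, which moves genes across the limit. TPM kept 688 of the 797 genes higher at 24 h, and 71 of its 84 lower genes were among the 217, so a shift alone does not account for it. The minimum of 1 TPM also differed from the one used with counts, and how much it accounts for was not tested.

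List medians under TPM, all on the log2 scale, moved as follows. Class switch recombination was 0.066 at 6 h and 0.10 at 24 h against 6 h. B cell identity was 0.19 at 6 h and 0.54 at 24 h. S phase was 0.064 at 6 h, -0.0705 at 24 h and -0.13 at 24 h against 6 h. G2 and M phase was 0.27, 0.26 and -0.022 in that order, and Myc and ribosome biogenesis -0.30, -0.66 and -0.26. Cholesterol synthesis was -0.12 at 6 h and 0.12 at 24 h. Interferon response was 1.10, glycolysis and hypoxia -0.12, T cell markers 0.99 and fibroblast and endothelial markers 2.29 at 24 h. Heat shock was -0.074 and housekeeping 0.081 at 6 h, and adhesion and homing receptors 0.26 at 24 h against 6 h. Under total counts, S phase was -0.012 at 6 h and -0.17 at 24 h, and G2 and M phase -0.052 at 24 h against 6 h. Myc and ribosome biogenesis was -0.37 at 6 h and -0.29 at 24 h against 6 h, and heat shock -0.15 at 6 h. Cholesterol synthesis was 0.016, T cell markers 0.88 and fibroblast and endothelial markers 2.16 at 24 h. Under CPM + 1, fibroblast and endothelial markers were 1.15 at 24 h. With the length trend removed, receptors, ligands and Smads were -0.034 at 24 h against 6 h, and housekeeping 0.030 at 6 h. With a minimum of 5 CPM, germinal centre was -0.091 at 24 h against 6 h, the 1 change of sign among lists that lay in the outer 5% of percentiles, and the cause was not tested. The other moves under total counts are the same shift of all genes, and the cause of the rest was not tested.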

Other observations

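Tests of the choice among scalings and of the split of Eif3j reads were chosen only after the result was seen, as were the genes named in the next paragraph and the liver X receptor and Notch lists.

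Apoe, a lipid carrier, had 139 CPM in control, 568 at 6 h and 1006 at 24 h, and the sterol exporter gene Abcg1 had 21.9, 75.0 and 61.1 CPM. Notch1 had 28.1, 64.0 and 106 CPM, and Rbpj, the DNA-binding partner of Notch, 307, 648 and 722 CPM. Ccng2, an atypical cyclin gene, had 9.05, 40.98 and 50.1 CPM, and Klhl24 had 22.7, 56.1 and 97.7 CPM. The galactosyltransferase gene B4galt1 had 164, 461 and 570.0 CPM, while the sialyltransferase gene St6gal1 had 37.5, 19.1 and 11.4 CPM. Il10, an anti-inflammatory cytokine gene, had 163, 89.4 and 72.5 CPM.

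Abca1 and Apoe might belong to a wider rise of liver X receptor targets, which control sterol export. The test planned for this used the 7 other measured targets at 24 h, and their median lay at percentile 85.5 of matched random lists, under the bound of 90 set beforehand. The 7 genes went both ways, from -0.62 (Scd1) to 1.48 (Abcg1) on the log2 scale, so their median decides nothing and the hypothesis stays open. At 6 h the same 7 genes lay at percentile 98.4, a value the plan did not use. Nrarp could likewise go with a wider rise of Notch targets. The 7 other measured targets lay at percentile 72.7 at 24 h, under the same bound, but they too went both ways, from -1.07 (Myc) to 4.24 (Notch3), which leaves this open as well.

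At 24 h, 3.67 times as many genes were higher than lower by the 2-fold rule, while at 1.5-fold the ratio was 1.42, so the asymmetry belongs to the larger differences. Background reads were argued against, since the upper bound of read density over odorant and vomeronasal receptor genes was 0.0014 of the median gain of the higher genes. After thinning to the depth of the 24 h library, the ratio had a median of 3.71 over 20 draws (3.585 to 3.943). With the median gene set to a ratio of 1 it was 3.90. Both ratios met neither bound set beforehand (under 2, over 5). The upper bound had been set from unscaled totals, where the ratio is 9.11, so TMM scaling alone put it out of reach. All thinned draws stayed above 2 and close to 3.67, which argues against unequal depth as the source of the split. Setting the median gene to 1 was a shift of only -0.011 on the log2 scale. That step could hardly move the ratio, so it says little about scaling. The lowest ratio over 5 scalings was 3.13, above a bound of 2.5 that was written after ratios had been seen. Time in culture cannot be told apart from TGFb. The labels give no time for the control, and no library is labelled as untreated at 24 h. The 30% of higher genes already counted at 6 h does not decide it.

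The log2 ratios went with transcript length, and this could reflect longer fragments in the treated libraries. The length that RSEM took off, as a median over the longer gene rows, was 170.3 nt in control, 172.5 at 6 h and 177.8 at 24 h. The deposited TPM take this length into account, and rho with TPM was still 0.38 at 24 h. However, the lengths taken off lay so close together that TPM could hardly lower rho, whatever the cause. The test thus speaks only against the length that RSEM took off, and other effects of fragment length were not tested. The length trend as the whole cause of the lower Myc and ribosome biogenesis genes was argued against, since their median was -0.81 after its removal. RNA quality, other effects of fragment length and a real preference for long or short mRNAs stay open, because no test here separates them.

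Eif3j2 was 12.3-fold lower at 24 h, and it shares reads with Eif3j1. The test planned beforehand asked whether Eif3j1 took up what Eif3j2 lost, and the gain was -0.075 of the loss, which argues against a plain transfer of reads between control and 24 h. Between 6 h and 24 h, a step the plan did not use, Eif3j1 gained 62.0 CPM while Eif3j2 lost 111 CPM, a share of 0.558 that lies between the 2 planned bounds (0.8 and 0.5), so a transfer over that step stays open. A test added after that result took the sum of both genes, which had 342 CPM in control, 247.5 at 6 h and 198 at 24 h and was 1.72-fold lower at 24 h, under 2-fold. However, Eif3j1 alone had 197 CPM in control. With Eif3j1 unchanged, even a complete loss of Eif3j2 would leave the sum less than 2-fold lower. The sum thus cannot tell a real loss of Eif3j2 from a split of reads by the estimation, and it does not undo the planned result. At 6 h the split was near even, at 125 and 123 CPM.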
